A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

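The series compares, on 2-colour spotted arrays, polyA RNA of yeast after 2 h of recovery from 16 h at 30 MPa and 25 °C (Cy5) with RNA of cells harvested at decompression (Cy3). It has 3 hybridizations of independent biological samples per the labels, and 5 deposited columns, because hybridizations 1 and 2 were scanned at a high and a low laser power to recover spots brighter than the scanning range. Every hybridization carries the dyes in the same order, so a dye effect on a gene cannot be separated from its change.

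The deposited values are log2 ratios, 1 per feature and scan. Per the labels' protocols, RNA was extracted with hot phenol, cDNA was primed with oligo dT and labelled by reverse transcription with dUTP dyes, and spots with a flag of 0 entered a LOWESS normalization by the authors. The labels also speak of a merged value of the high and low scans, which is not among the columns analysed here. The base of the logarithm was read from the values: the lowest value, found once, in hybridization 3, is the log2 of 0.01. The direction of the ratio is not given in the sources used here and was taken as Cy5 over Cy3. Column medians ran from -0.01 to 0.01, so the columns are close to centred on 0. The genome build of the array design is not given in the sources used here, so no coordinates are printed.

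The platform annotation named 5297 of 6336 features with 1 gene each and none with several; 1039 had no name and were counted but not named. Of the named features, 5293 matched the RefSeq gene table of assembly R64 by Entrez identifier. Features of one gene were averaged; 88 genes had more than 1 feature, and for 67 of these, ACT1 with 13 features among them, the deposited values were identical in every column. The high and low scans of a hybridization were averaged, which leaves 1 value per hybridization. Scans of one hybridization correlated across genes with Pearson r = 0.95 (hybridization 1) and 0.90 (hybridization 2).

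Each gene's mean log2 ratio was tested against 0 with limma (lmFit with an intercept, eBayes; limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment over the 1891 genes and unnamed features that had a value in all 3 hybridizations (1832 named genes and 59 unnamed features), at an adjusted p of 0.05, on both sides. The prior had 12.2 degrees of freedom, and the median standard error was 0.25. No pseudocount, floor or further centring was applied. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 32 lists with at least 5 tested members, beside camera with an estimated correlation and fry. A list's shift is its median minus the median of all tested genes, which was 0.09. The design, the 36 gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

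The rule for named genes took, in each direction, the 12 genes with the largest mean among those that passed with the same sign in all 3 hybridizations; for each list described, up to 4 members with the smallest p, at most 2 in each direction; and a fixed set of stress, cell cycle, ribosome and membrane genes. From the fixed set, HSP26, SSA4, CTT1, TAT2, DAN1 and TIR1 had values in fewer than 3 hybridizations and were left out of the main test. All of these but SSA4 entered the fit over genes with at least 2 hybridizations. In that fit the standard errors of genes with 2 values hardly followed their own spread. KDX1 (SD 0.0013) had a standard error of 0.303 and EPS1 (SD 1.59) one of 0.306. The p-values of such genes therefore rest almost only on the mean ratio and the pooled variance. ATG8 was named outside the rule, after its value was seen.

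The steps were tested on simulated data: 20 simulated sets of 1891 genes with 200 changed. Of genes changed by a log2 of 0.5, 1, 1.5 and 2, 10.7%, 69.3%, 97.8% and 99.9% were recovered, and 4.5% of calls were false. A list shifted by 0.5 was called by camera in 100% of the sets and in 0% with an estimated correlation. Larger shifts were not simulated. Simulated genes varied independently, so these sets do not show how camera at its preset correlation behaves when members of a list are correlated. In the data, the estimated correlations of the 17 lists past camera ran from -0.18 (hexose transporters) to 0.41 (histones). A plain one-sample test made 0.05 calls per set on average. When a trend of -0.5 per doubling of coding length was added over the 1832 genes with a length, 240 unchanged genes were called per set on average, and 6.3 after the length correction. That slope was a chosen setting and was not fitted to the data. The 240 therefore does not estimate how many of the calls in the real data come from the length trend.

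Alternatives were each scan alone, the 5 scans with the hybridization as a random block, centring and scaling, array weights, other rules on missing values, a robust prior, the plain one-sample t-test, each feature on its own, the gene at the floor left out, and each hybridization left out in turn. Alternatives added after the data were seen were centring on ACT1, hybridizations 1 and 2 alone over all their genes, a correction for coding length, centring within groups of features, and the last 2 together. For the length correction, each hybridization's lowess trend (span 0.5) on log2 coding length in R64 was subtracted; all tested members of the lists had a length, 97.3% of lengths were multiples of 3, and unnamed features dropped out. For position, the medians of 48 groups of features that share the first 3 digits of their number were subtracted. That these groups are places on the array was assumed. The last 2 digits were not corrected for, so every value given as corrected for position is corrected for the leading digits only. Some tests of explanations for the closing section were run and, after their results were seen, left out of the weighing, which was held to 3 patterns. These were tests on dim features (cell cycle genes with a value in all 5 scans lay 0.96 above all genes), on ACT1 against 6 other reference genes (median log2 ratio -0.16, bootstrap SE over genes 0.20) and on position for the glycolysis list (shift -0.81 after centring within groups of features). The test of saturation was run in 3 forms. The first, over 9 glycolysis genes with a value in all 5 scans, gave medians of -1.09 in the high and -0.98 in the low power scan of hybridization 1, -0.61 and -0.68 in those of hybridization 2, and 0.15 in hybridization 3. The second took every glycolysis gene with both scans, a choice made after the first result, and gave -0.86 and -0.55 in hybridization 1 (14 genes) and -0.66 and -0.88 in hybridization 2 (13 genes). Both ask whether saturation changed the size of the fall. The third, given in the closing section and chosen after the others, asks whether the fall is present in the low power scans alone. The labels give no scan date or slide. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.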

Results

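Transcript levels of budding yeast (Saccharomyces cerevisiae) were measured after release from high hydrostatic pressure. Exponentially growing cells were held for 16 h at 30 MPa and 25 °C, then brought back to atmospheric pressure (0.1 MPa) and left to grow for 2 h. Their polyA RNA, labelled with Cy5, was hybridized on a 2-colour spotted array together with Cy3-labelled RNA of cells harvested right at decompression (0 h). The series holds 3 hybridizations of independent biological samples, each with recovery and decompressed RNA on the same array. Hybridizations 1 and 2 were scanned at high and at low laser power and hybridization 3 once, which gives 5 scans. Of the 6336 features, 4324 and 3662 carried a value in the high and low power scans of hybridization 1, 5007 and 4017 in those of hybridization 2, and 2089 in hybridization 3 (33.0%).

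The comparison asks which transcripts differed between cells 2 h into recovery and cells just decompressed. Values are log2 ratios, and the labels do not say which channel is the numerator. Recovery over decompressed, the first channel of the labels over the second, was taken as the likely direction, and every direction given here would swap if the ratio ran the other way. Among 1891 genes and unnamed features with a value in all 3 hybridizations, 515 changed (27.2%), of which 285 were higher and 230 lower in recovery (limma, adjusted p threshold 0.05). The change was at least 2-fold for 244 of them, 130 higher and 114 lower. The sign was the same in all 3 hybridizations for 1054 of all tested (55.7%), where independent signs would give 25%. A length trend or dye effect shared by the hybridizations would also raise that share. Among the 515 it was the same for 510, but these were called from the same 3 values, so this is no separate support. Centring each hybridization on its median turned the balance to 233 higher and 277 lower (45.7% higher). Without hybridization 1 the count was 240 (115 higher, 125 lower), without hybridization 2 it was 319 (155 higher, 164 lower) and without hybridization 3 it was 427 (263 higher, 164 lower). Across the 1891 genes, which are not independent replicates, the ratios of hybridizations 1 and 2 correlated with Pearson r = 0.72, those of 1 and 3 with 0.59 and those of 2 and 3 with 0.55.

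Among named genes called with the same sign in all 3 hybridizations, CIN5 (YOR028C), a transcription factor of the AP-1 family, rose most in recovery. Its mean log2 ratio was 2.56 ± 0.54 (SD, n = 3, limma adjusted p = 4.95e-05). Genes without a value in all 3 hybridizations were not ranked. AIM20 (YIL158W) rose by 2.52 ± 0.20 and BNS1, a relative of the mitotic exit gene SPO12, by 2.24 ± 0.27. ICY1 and ISF1 each rose by 2.17, with SDs of 0.49 and 0.54. The histone H4 gene HHF1 rose by 1.99 ± 0.08 and MPC3, a subunit of the mitochondrial pyruvate carrier, by 1.98 ± 0.14. The cell surface genes SRL1, GAS3 and SCW11 rose by 2.01 ± 0.93, 1.89 ± 0.29 and 1.78 ± 0.50. RNH203, a subunit of ribonuclease H2, rose by 1.97 ± 0.30 and STP4 by 1.77 ± 0.45.

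In the other direction, again among named genes called with the same sign in all 3 hybridizations, MET6 (YER091C), the methionine synthase, fell most. Its mean log2 ratio was -3.49 ± 0.46 (SD, n = 3, limma adjusted p = 2.53e-06), an 11.3-fold difference. PDC1 (YLR044C), the main pyruvate decarboxylase of fermentation, stood at -2.95 ± 0.69 and OPI3, a methyltransferase of phosphatidylcholine synthesis, at -2.32 ± 0.28. MET17 of sulphur assimilation stood at -2.25 ± 0.43 and SAM2, an S-adenosylmethionine synthetase, at -2.20 ± 0.04. The amino acid enzymes SHM2 and SER3 fell to -1.98 ± 0.68 and -1.89 ± 0.21. The oxidase of the endoplasmic reticulum ERO1 stood at -2.00 ± 0.47, the cell wall gene PST1 at -2.17 ± 0.41 and the phosphatase gene PTP2 at -1.90 ± 0.25. The riboflavin transporter MCH5 stood at -2.27 ± 0.24 and YPL088W at -1.91 ± 0.31. All 24 genes named here as largest in either direction passed the test without any 1 hybridization and after a correction for coding length; corrected for position and coding length together, RNH203 was at 1.09 and still passed.

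**Figure D1:**
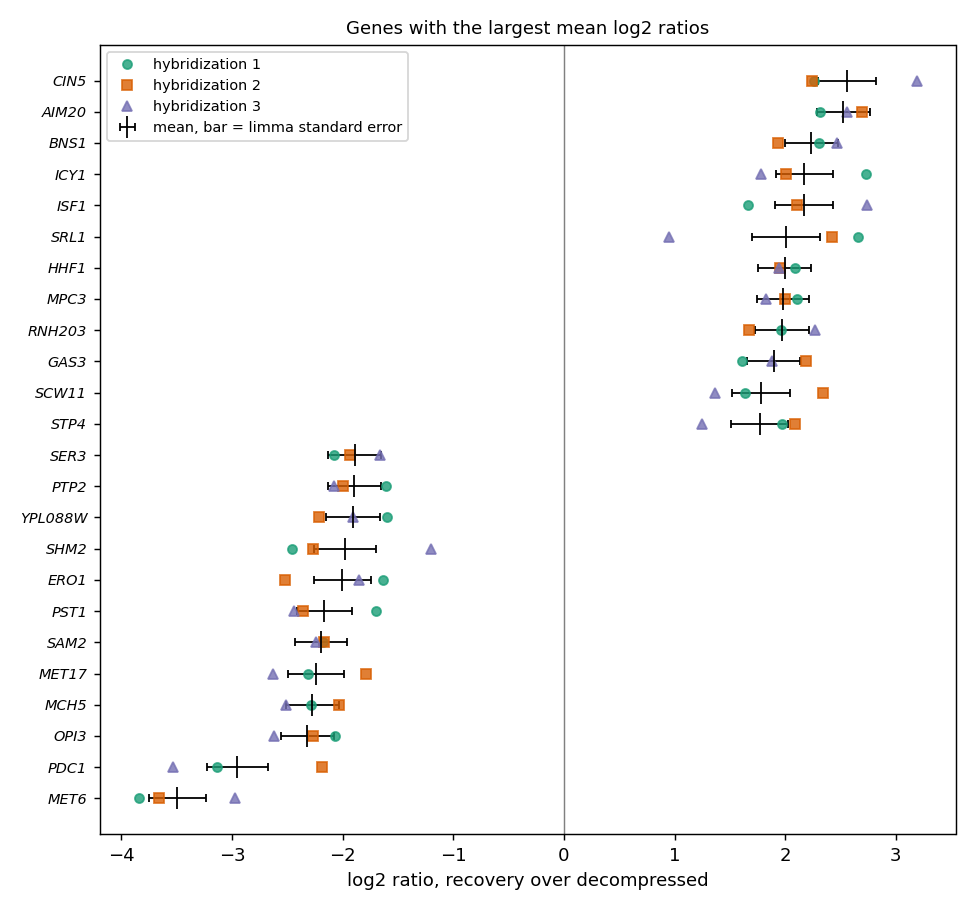
Log2 ratio of recovery over decompressed on the x axis for the 12 genes with the largest mean in each direction, among named genes called with the same sign in all 3. Coloured points are the 3 hybridizations, black ticks the mean and bars the limma standard error. CIN5 sits at 2.26, 2.24 and 3.19 and MET6 at -3.84, -3.66 and -2.98.

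A shift that ran across all genes bears on the groups that follow. In each hybridization the log2 ratio fell with coding length, with Spearman rho of -0.48 over 4151 genes in hybridization 1, -0.24 over 4738 in hybridization 2 and -0.23 over 1988 in hybridization 3. In the mean of the tested genes the shortest 10% had a median log2 ratio of 0.54 and the longest 10% -0.25. Genes called higher had a median coding length of 696 bases and genes called lower 1364. After each hybridization's trend on length was removed, 411 of 1832 genes passed, 201 higher and 210 lower, and 338 of these were among the 515. Only 263 of those called higher and 226 of those called lower had a length and could pass again.

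**Figure D2:**
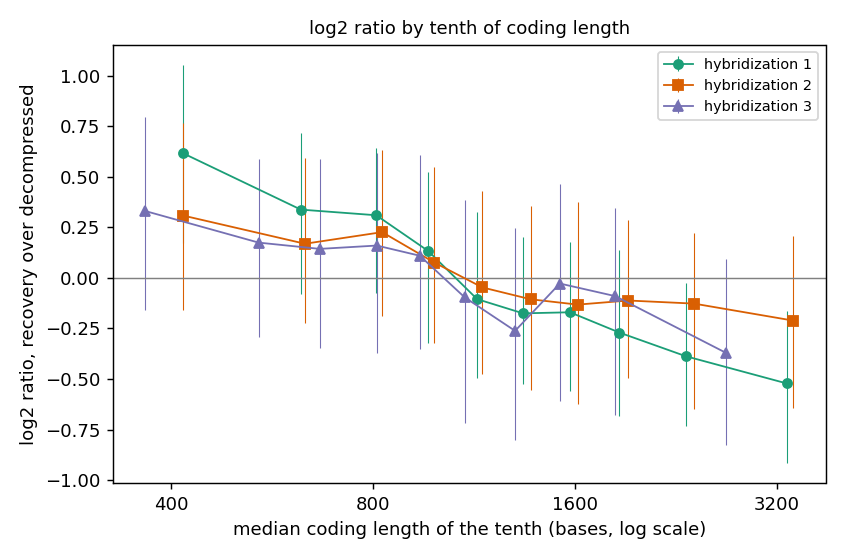
Median log2 ratio of recovery over decompressed for genes in 10 bins of coding length, on a log axis of bases, for each hybridization; bars are interquartile ranges. In hybridization 1 the medians run from 0.62 for the shortest genes to -0.52 for the longest, in hybridization 2 from 0.31 to -0.21, and in hybridization 3 from 0.33 to -0.37.

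Genes of mitotic exit and daughter cell separation rose in recovery. Of 15 tested, 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 ratio of 1.12. SCW11 at 1.78 and EGT2 at 1.72 ± 0.35 were among them; both are expressed at the end of mitosis and act in the cell wall. The exception was PIR3, a cell wall protein gene, at -1.68 ± 0.21, and PIR1 had a value of -0.30 that did not pass. Mitosis genes rose as well, 4 of 7 with none lower (5 of 7 adjusted over the list alone), among them the B-type cyclin genes CLB1 at 1.47 ± 0.26 and CLB2 at 1.04 ± 0.15. Without hybridization 1, CLB2 was at 0.96 and missed the threshold (adjusted p = 0.0673). Over genes with at least 2 hybridizations the mitosis counts were 7 higher and 2 lower of 23, at a median of 0.43; the lower ones, ASE1 at -1.37 and DBF2 at -0.92, were chosen after their values were seen. In camera, the set test of limma, the adjusted p was 0.00249 for the mitotic exit list and 0.00965 for the mitosis list, and adjusted p = 0.407 for both with an estimated correlation. After the correction for coding length both lists still passed, with shifts against all genes of 1.11 and 0.93.

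Histone genes rose in recovery, 5 of 6 tested with none lower, at a median log2 ratio of 1.05 (5 adjusted over the list alone). HHF1 and HHF2, which encode the same histone H4 and whose signals can mix on an array of this kind, rose 3.98-fold and 2.82-fold (log2 SDs of 0.08 and 0.45). The H2A gene HTA1 stood at 1.04 ± 0.67, at 0.94 without hybridization 1 and at 0.77 without hybridization 2, and missed the threshold in both cases (adjusted p = 0.0879 and 0.126). Camera gave the list an adjusted p of 0.00278, and adjusted p = 0.407 with an estimated correlation. These are short genes, and after the correction for coding length their shift fell from 0.95 to 0.62, with 2 of 6 still called and an adjusted p of 0.02 for the list. HTA1 was then at 0.66 (adjusted p = 0.087), at 0.61 after centring within groups of features (adjusted p = 0.163) and at 0.23 after both corrections (adjusted p = 0.548). The list of G1/S cyclins and DNA replication did not pass; limma called 0 of 8 and 0 had an unadjusted p under 0.05, with CLN2 at 0.36 ± 0.24 and the replication clamp gene POL30 at 0.49 ± 0.28.

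Genes of oxidative phosphorylation rose in recovery. Of 27 tested, 16 rose and none fell (18 and 1 adjusted over the list alone), with a median log2 ratio of 0.79 and medians of 0.87, 0.67 and 0.85 in the 3 hybridizations. QCR7, a subunit of the cytochrome bc1 complex, rose by 1.56 ± 0.21 and CYC7, a cytochrome c gene, by 1.45 ± 0.13. STF2, at -0.59 ± 0.39, did not pass. Camera gave an adjusted p of 8e-06, and adjusted p = 0.407 with an estimated correlation. After the correction for coding length 10 of these genes were called higher and 1 lower, STF2 at -1.13, and the shift of the list went from 0.70 to 0.60 (adjusted p = 0.000514). The tricarboxylic acid cycle list did not pass (2 higher and 1 lower of 12; 3 and 2 adjusted over the list alone), although the succinate dehydrogenase genes SDH2 and SDH3 were called at 0.85 ± 0.23 and 0.84 ± 0.17; without hybridization 1 they missed the threshold (adjusted p = 0.098 and 0.12), and without hybridization 2 as well (adjusted p = 0.122 and 0.103). SDH3 also missed it after the correction for coding length, at 0.59 (adjusted p = 0.074). The member called lower was PYC1, at -0.82 ± 0.45 (limma adjusted p = 0.0283), and at -0.42 after that correction (adjusted p = 0.204). PYC1 also missed the threshold without hybridization 1 (limma adjusted p = 0.173) and without hybridization 3 (adjusted p = 0.111). Over genes with at least 2 hybridizations 3 of 17 members of this list rose and 5 fell (camera adjusted p = 0.985).

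Hexose transporter genes rose and genes of glycolysis and ethanol fermentation fell. Of 6 transporters tested, 4 rose and none fell (6 adjusted over the list alone), with HXT5 at 1.32 ± 0.16 and HXT2 at 1.30 ± 0.24. Of 20 glycolysis and fermentation genes, 10 fell and none rose (11 adjusted over the list alone), at a median log2 ratio of -0.73. PDC1 was lowest, and ADH2, an alcohol dehydrogenase known for ethanol use, stood at -1.54 ± 0.57; the hexokinases HXK1 and HXK2, at 0.22 and 0.03, did not pass. ADH2 resembles ADH1, and the HXT genes resemble one another, so that cross-hybridization within these families stays open. Camera gave adjusted p values of 0.00395 and 3.44e-06, and adjusted p = 0.407 for both with an estimated correlation. After the correction for coding length the shifts were 1.06 and -0.78, and both lists passed.

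Genes of methionine and sulphur metabolism fell in recovery, 7 of 12 tested with 1 higher (the same counts adjusted over the list alone), at a median log2 ratio of -1.18. MET6, MET17 and SAM2 were lowest, and SAM4, a homocysteine methyltransferase gene, was higher at 0.98 ± 0.35. SAM4 missed the threshold without hybridization 1 (adjusted p = 0.0571) and without hybridization 2 (adjusted p = 0.0968). Over genes with at least 2 hybridizations 12 of 27 fell and 1 rose, and the shift of the list was -0.53 against -1.27. SAM1 and SAM2 are near-identical copies, which an array of this kind need not separate. Of 30 genes for the synthesis of other amino acids, 16 fell and 1 rose (also 16 and 1 adjusted over the list alone), at a median of -0.79. The shift of that list was -0.88, and it was -0.71 after the correction for coding length, -0.70 after that for position and -0.51 after both, where it passed each time. SER3 at -1.89 and ARG4, argininosuccinate lyase, at -1.82 ± 0.31 had the smallest p values among these. Camera gave both lists an adjusted p of 1.15e-05, and adjusted p = 0.407 for both with an estimated correlation. The lists of amino acid permeases (0 higher and 1 lower of 12) and of aminoacyl-tRNA synthetases (1 and 1 of 19) did not pass, with the same counts adjusted over each list alone. Over genes with at least 2 hybridizations 1 permease rose and 5 fell of 21, and 1 synthetase rose and 6 fell of 21. Neither list passed there (camera adjusted p = 0.267 for each). Of the permeases, the methionine transporter MUP1 fell to -1.25 ± 0.53, and TAT1, a tyrosine and tryptophan transporter, was at 0.42 ± 0.29 without a call.

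Genes of protein folding in the endoplasmic reticulum fell. Of 13 tested, 6 fell and 1 rose (6 and 2 adjusted over the list alone), at a median log2 ratio of -0.52. ERO1 stood at -2.00, PDI1, protein disulphide isomerase, at -1.81 ± 0.24, and the Hsp70 chaperone KAR2 at -1.55 ± 0.36. SSS1, a translocon subunit and the only riser, was at 0.71 ± 0.40, and at 0.15 after the correction for coding length (adjusted p = 0.705); it also missed the threshold without hybridization 1 (adjusted p = 0.209) and without hybridization 2 (adjusted p = 0.289). Over genes with at least 2 hybridizations 7 of 22 fell and 2 rose, and the shift of this list was -0.31 against -0.61. Membrane lipid genes fell too, 7 of 17 for fatty acids and phospholipids and 5 of 17 for ergosterol, with none higher in either list (the same counts adjusted over each list alone). The shift of the fatty acid and phospholipid list was -0.61, and -0.31 after centring within groups of features, where it still passed. OPI3 at -2.32, the inositol transporter ITR1 at -1.39 ± 0.46 and the desaturase OLE1 at -1.17 ± 0.21 fell in the first group. ERG25 was at -0.93 ± 0.48 and ERG3 at -0.97 ± 0.62 in the second, and both missed the threshold without hybridization 1 (adjusted p = 0.166 and 0.068) and without hybridization 3 (adjusted p = 0.0762 and 0.0974). Camera gave adjusted p values of 0.00616, 0.00327 and 0.0107 for the 3 lists, and adjusted p = 0.407 for each with an estimated correlation. With every gene measured in hybridizations 1 and 2 alone, the ergosterol list no longer passed (adjusted p = 0.215), and over genes with at least 2 hybridizations its shift was -0.40 against -0.64 (8 of 22 lower). Centred on ACT1, the medians of these 3 lists turned to 0.06, 0.05 and 0.03.

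Cytosolic ribosomal protein genes were slightly higher in recovery. Of 107 tested, 23 rose and none fell (22 adjusted over the list alone), at a median log2 ratio of 0.44, and 95 had a mean above 0. RPL23B stood at 1.34 ± 0.06 and RPL26A at 1.12 ± 0.06, while RPL3, at -0.04 ± 0.11, and RPS3, at 0.39 ± 0.48, did not pass. Across the alternatives the lowest values of RPL23B and RPL26A were 0.85 and 0.53. Most of these genes have a near-identical paralog, so single members are uncertain. Camera gave an adjusted p of 3.22e-05, and adjusted p = 0.407 with an estimated correlation. After the correction for coding length the shift fell from 0.35 to 0.19 (adjusted p = 0.00518) and 13 were called higher and 2 lower, RPL15A at -0.71 and RPL15B at -0.76. Mitochondrial ribosomal protein genes, 7 higher and 1 lower of 29 (11 and 1 adjusted over the list alone), passed camera at an adjusted p of 0.0166, with adjusted p = 0.641 for an estimated correlation. That call ended after the correction for coding length, where the shift fell from 0.42 to 0.27 (adjusted p = 0.35) with 0 higher and 2 lower, and it ended without hybridization 1 (adjusted p = 0.204). MRP2, at 0.98 ± 0.39, lost its call after the correction too (0.54, adjusted p = 0.108; 0.18 with position corrected as well), and without hybridization 1 (adjusted p = 0.104) or 2 (adjusted p = 0.0802). The list of ribosome biogenesis did not pass (6 higher and 9 lower of 80; 5 and 5 adjusted over the list alone), with NSR1 at 0.16 ± 0.63. Over genes with at least 2 hybridizations the counts of that list were 8 higher and 33 lower of 121 (adjusted p = 0.0936), and with hybridizations 1 and 2 alone it passed (shift -0.19, adjusted p = 0.0202). Translation factors (1 higher and 2 lower of 26; 0 and 2 over the list alone) and RNA polymerase I and III subunits did not pass either; for the polymerases limma called 0 of 11, and 0 had an unadjusted p under 0.05.

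Decreases were also found in the phosphate regulon, in autophagy and vacuolar protease genes and in the actin cytoskeleton. PHO11, an acid phosphatase gene, stood at -1.03 ± 0.42 and PHM8 at -0.97 ± 0.38, 2 of the 4 that fell among 8 phosphate genes tested; PHO11 missed the threshold without hybridization 2 (adjusted p = 0.0963) and PHM8 without hybridization 3 (adjusted p = 0.0533). The vacuolar proteases PRC1 and PEP4 stood at -1.36 ± 0.24 and -1.33 ± 0.41, and with ATG8 at -0.78 ± 0.41, chosen after its value was seen, made 3 of 6 genes lower. ARP2, a subunit of the actin-nucleating Arp2/3 complex, stood at -1.20 ± 0.41, 1 of 4 lower among 16 actin and tubulin genes, and ACT1 itself was at -0.58 ± 0.18 without a call (adjusted p = 0.0874). ACT1 was called lower after centring within groups of features (-0.58, adjusted p = 0.0327), with each hybridization centred on its median (-0.67, adjusted p = 0.047) or also scaled (-0.68, adjusted p = 0.0445), and with array weights (-0.63, adjusted p = 0.0384). Cell wall genes went both ways, 10 lower and 4 higher of 29, with HSP150 at -1.68 ± 0.06 and CWP1 at 1.62 ± 0.38. Counts adjusted over each list alone were the same for these 4 lists. Camera gave adjusted p values of 0.0107, 0.0119, 0.019 and 0.0172 in this order, and with an estimated correlation adjusted p = 0.407, 0.407, 0.407 and 0.575. The actin call was lost without hybridization 1 (adjusted p = 0.0663) and without hybridization 2 (adjusted p = 0.0681), and the cell wall call without hybridization 1 (adjusted p = 0.0681) and when position and coding length were corrected together (adjusted p = 0.0696). The cell wall call was also lost with the high power scans only (adjusted p = 0.141), with a value in at least 2 hybridizations (0.112), with a value in all 5 scans (0.161) and with hybridizations 1 and 2 alone (0.249). The call of the autophagy and vacuolar protease list was lost with hybridizations 1 and 2 alone (adjusted p = 0.0828), and over genes with at least 2 hybridizations 3 of 16 of these genes were lower (shift -0.45 against -0.68), and the actin call with centring on ACT1 (adjusted p = 0.0509). Centred on ACT1, the medians of the actin and cell wall lists turned to 0.20 and 0.28.

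General stress genes had more decreases than increases, but the stress lists did not pass camera in the test over all 3 hybridizations. Of 15 general stress genes of the Msn2/Msn4 type, 6 fell and 1 rose (also adjusted over the list alone), and camera gave an adjusted p of 0.0723. YGP1 fell to -1.68 ± 0.66 and DDR48 to -1.20 ± 0.16, whereas MRK1 rose to 1.71 ± 0.95. The small heat shock gene HSP12 was at -0.91 ± 0.94 and passed (adjusted p = 0.043), but not without hybridization 1 (adjusted p = 0.0756) or without hybridization 2, where it was at -0.39 (adjusted p = 0.448). Without hybridization 3 the general stress list passed (adjusted p = 0.0306), as did the aminoacyl-tRNA synthetases (adjusted p = 0.00934) and trehalose and glycogen metabolism (adjusted p = 0.04). The general stress list also passed camera with array weights (adjusted p = 0.0446) and with each feature on its own (0.0315). In the latter a gene with several features can count more than once, and DDR48 has 2. It passed as well with a value in at least 2 hybridizations (0.0168, with 10 lower and 1 higher of 27) and with hybridizations 1 and 2 alone (0.00217). The aminoacyl-tRNA synthetases passed with hybridizations 1 and 2 alone as well (adjusted p = 0.0185). Among 16 cytosolic heat shock and co-chaperone genes 3 fell, HSP104 at -1.26 ± 0.44 among them, and 1 rose, the Hsp40 gene SIS1 at 1.11 ± 0.30. Over genes with at least 2 hybridizations the balance of this list turned to 5 higher and 4 lower of 23 (camera adjusted p = 0.71). HSP30 was at -0.13 ± 0.57 and the trehalose synthase TPS1 at -0.32 ± 0.43, both without a call. The other lists did not pass camera, with 1 higher and 2 lower of 9 for trehalose and glycogen, 3 and 4 of 20 for antioxidant enzymes (4 and 4 over the list alone), and 0 and 2 of 28 for the proteasome (0 and 1 over the list alone). Limma called 0 of 5 genes each for mitochondrial chaperones, the iron regulon and DNA damage, where 2, 1 and 0 had an unadjusted p under 0.05. Signs of median and set test differed for the amino acid permeases, antioxidant enzymes, the proteasome, RNA polymerase I and III, translation factors and trehalose.

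**Figure D3:**
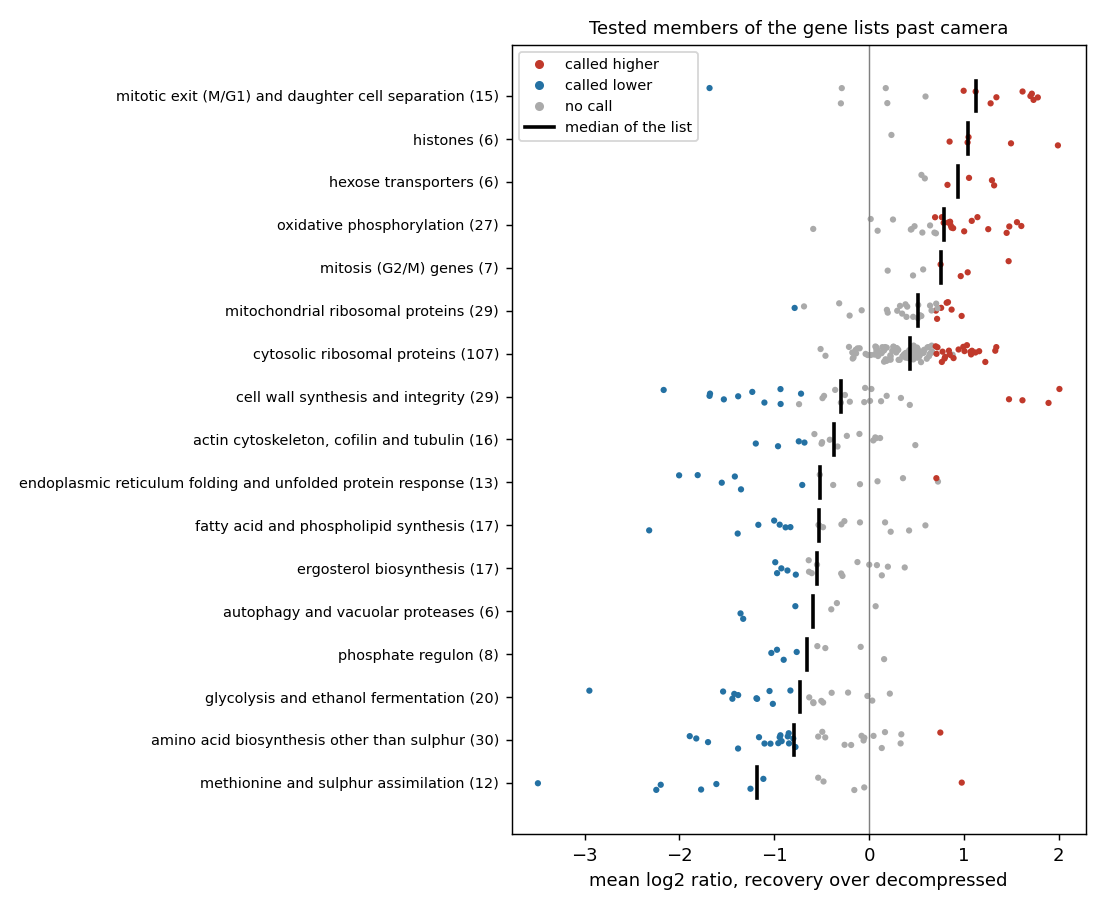
Mean log2 ratio of recovery over decompressed on the x axis for each tested member (points) of the 17 gene lists that passed camera, with the number tested in brackets; black ticks are list medians and colours mark calls. Medians run from 1.12 for mitotic exit and daughter cell separation to -1.18 for methionine and sulphur assimilation; centred on ACT1, those of 5 of the lower lists turn positive.

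Of 32 lists with at least 5 tested members, 17 passed camera, 7 higher and 10 lower; 0 passed with an estimated correlation (2 at an unadjusted p under 0.05) and 8 passed fry, which does not compare a list with other genes. The 9 that missed the threshold in fry were glycolysis and histones (adjusted p = 0.0695 each), endoplasmic reticulum folding (0.07), fatty acids and phospholipids (0.0719), cytosolic ribosomal proteins (0.0877), autophagy and vacuolar proteases (0.0886), cell wall (0.157), mitochondrial ribosomal proteins (0.168) and ergosterol (0.196). When each hybridization was centred on ACT1, 967 genes passed, 900 higher and 67 lower (93.1% higher against 55.3%), because the median of all genes moved by 0.58 on the log2 scale, and the list medians for actin, cell wall, ergosterol, fatty acids and phospholipids, endoplasmic reticulum folding, Msn2/Msn4, heat shock, mitochondrial chaperones, aminoacyl-tRNA synthetases and ribosome biogenesis turned positive.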

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

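Alternatives chosen after the result was seen were ACT1 centring, hybridizations 1 and 2 alone over all their genes, and the corrections for coding length and position. No named gene and no list turned its direction with a call in any alternative run. For lists this is the direction in camera, which compares with other genes. Subtracting a constant from all genes of a hybridization can hardly turn it. The medians of the actin, cell wall, ergosterol, fatty acid and phospholipid, and endoplasmic reticulum folding lists did turn positive with ACT1 centring. The count of 515 stayed between 408 (low power scans) and 646 (array weights) under the other settings for scans, centring, prior, features and floor. It was 1198 over 4368 genes with at least 2 hybridizations (585 higher, 613 lower, 511 at least 2-fold) and 1052 over 4213 genes with hybridizations 1 and 2 (508 higher, 544 lower, 513 at least 2-fold), where more genes were tested. In the fit with at least 2 hybridizations, calls of genes with 2 values rest almost only on their mean ratio and the pooled variance. ACT1 centring gave 967 (900 higher, 67 lower, 564 at least 2-fold), by its shift of all ratios. The plain one-sample t-test called 0 (429 at an unadjusted p under 0.05, smallest adjusted p 0.0977), and 105 genes were at least 2-fold the same way in each hybridization. Leaving out 1 hybridization gave 240 to 427 genes, 115 to 263 higher and 125 to 164 lower, 240 to 293 at least 2-fold, and 14 to 20 lists; fewer samples enter these fits. The correction for coding length gave 411 genes and 16 of the 17 lists, the position correction 628 genes and all 17, and both together 572 genes and 15 of the 17 lists. Of the 515 calls, 338, 451 and 377 were kept in these 3 settings, so the genes called changed more than the counts. Unnamed features, 22 called higher and 4 lower among the 515, have no length and could not be kept where length was corrected. Medians of the 48 groups of features had SDs of 0.18, 0.38 and 0.38 in hybridizations 1, 2 and 3. The highest SDs in 1000 shuffles of the features were 0.13, 0.10 and 0.20. The largest absolute group median was 1.03, in hybridization 3. Of the 17 lists, 0 passed camera with an estimated correlation and 8 passed fry. In simulated sets, where genes varied independently, a list shifted by 0.5 was called in 0% with an estimated correlation. Why fry called fewer lists was not tested. Signal over background is not part of the values used here, so what dim spots limit was not examined beyond the missing values.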

Other observations

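Genes of the fixed set without a value in all 3 hybridizations were left out of the main test. In the fit over genes with at least 2 hybridizations, DAN1 and HSP26 were called lower (limma adjusted p = 6.94e-05 and 0.0221) and TIR1 higher. CTT1 and TAT2 were not called there, and SSA4 was not tested. Calls in that fit of genes with 2 values hardly take the spread of these values into account. In hybridizations 1 and 2 the anaerobic cell wall genes TIR1 and DAN1 were at 0.92 and 1.06 and at -1.48 and -1.34, the heat shock gene HSP26 was at -0.75 and -0.97, and the tryptophan permease gene TAT2 was at -0.07 and 0.25. The catalase gene CTT1 was at 0.11 and 0.78 in hybridizations 2 and 3, and the Hsp70 gene SSA4 was at -0.79 in hybridization 1. The following values were chosen after they were seen. The phosphate regulon genes VTC3, PHO84, VTC4 and VTC2, which serve polyphosphate synthesis and phosphate uptake and have no value in hybridization 3, had log2 ratios of -2.97 and -3.09, -2.88 and -2.59, -2.25 and -2.09, and -1.40 and -1.79 in hybridizations 1 and 2. Over genes with at least 2 hybridizations, 10 of 15 genes of the phosphate regulon were lower and none higher (camera adjusted p = 1.37e-07). In the same fit, 4 of 7 genes of the mating pheromone response were lower and none higher (camera adjusted p = 0.00976). Both camera values hold at the preset correlation, and an estimated correlation was not run in this fit. In the main test the phosphate list did not pass with it (adjusted p = 0.407), and the mating list was too small to test. Of the 4 mating genes with all 3 values, KAR4, STE12 and STE3 had means of -1.32, -0.79 and -0.72 and were called lower. FUS3, at -0.33, was not called.

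The tests of position within the length trend and of scan saturation were chosen after the result was seen, as were the dye test of the last pattern and the test of the sign patterns. Turning the sign of 1 hybridization at a time gives 4 patterns, and 1 of the 4, the real one, called as many as 515 genes; the highest other called 0. With 4 patterns no share under 0.05 can be had.

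The fall of the log2 ratio with coding length was seen in each hybridization. It is not carried by the short genes of the lists that shifted, since over 1193 genes in none of the lists Spearman rho was -0.36 (bootstrap SE 0.026). Position was tested here only through the last 2 digits of the feature number, which sort with length (rho = 0.66). That these digits mark a place on the array was assumed. Within 11 groups of features that share them, the mean rho with length was -0.19 (SE 0.045). Within 10 bins of length, the mean rho with the digits was -0.085 (SE 0.014). The last 2 digits therefore do not account for all of the fall. The leading digits were not held fixed, so position as a whole stays open. A dye effect on cDNA of different length stays open, because 0 hybridizations had swapped dyes, and a difference in RNA integrity or in reverse transcription between recovery and decompressed RNA was not tested. No biological explanation was tested.

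Cell cycle lists were higher in recovery: mitotic exit, mitosis and histones. The coding length trend is argued against as the whole cause for mitotic exit and mitosis. Its removal did not lower their shifts, which went from 1.03 to 1.11 and from 0.66 to 0.93. The histone shift fell from 0.95 to 0.62, by more than the 0.244 allowed before the test, so part of the histone rise may come from that trend. Position on the array was tested on the mitotic exit list, whose shift was 1.00 after centring within groups of features. A dye effect cannot be told apart from the change, with 0 dye-swapped hybridizations. The hypothesis that cells resumed division during the 2 h of recovery stays open and untested, as do counts of cells or buds that would test it.

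Oxidative phosphorylation and hexose transporter genes were higher and glycolysis genes lower. Removal of the length trend took their shifts from 0.70, 0.85 and -0.82 to 0.60, 1.06 and -0.78, each past the threshold. The trend is therefore argued against as their whole cause, and its removal did not lower the hexose transporter shift. Saturation of bright spots is argued against as the whole cause of the glycolysis fall in hybridizations 1 and 2, as far as the low power scans are free of it. There the list had shifts of -0.94 (SE 0.158) and -0.80 (SE 0.347) in hybridizations 1 and 2. These are SEs of the list median from resampling its genes within 1 scan, not replicate errors. Hybridization 3 was scanned once, so saturation was not tested there. Its median over the 20 tested glycolysis genes was -0.64, but it was 0.15 over the 9 with a value in all 5 scans. The low minus the high power median over genes with both scans, 0.31 and -0.22, leaves open whether saturation changed the size of the fall. A candidate explanation is lower glucose at 2 h of recovery. Genes of gluconeogenesis, the glyoxylate cycle and beta-oxidation, repressed by glucose, were taken over genes with at least 2 hybridizations. Their shift was 0.0121 (bootstrap SE over genes 0.089, 14 genes, camera adjusted p = 0.67), which does not decide it. The recovery itself stays open, and a dye effect cannot be told apart from it, with 0 dye-swapped hybridizations.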
